A study of Mus musculus with 8 samples.

How the data were processed

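Bulk RNA-seq was made from 4 Control and 4 FGFR1-CKO libraries of flushed femoral cortical bone. Per the labels' protocols, ribosomal RNA was removed with RNase H, cDNA was primed with random hexamers, and paired reads were sequenced. Groups follow the genotype labels. Replicate numbers are accession order and pair nothing. The labels do not say that each library came from a different mouse, so limma and permutation p-values measure the spread between these samples, which may be technical. They give no batch and no sex.

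The submitters' processing notes name cutadapt, STAR 2.7.9a, featureCounts, Subread 2.0.1, RSEM, edgeR, DESeq2 and the mm10 build, without saying which step each served. The authors' annotation version and use of strand are not given in the sources used here. The authors deposited 1 workbook for the comparison. Its main sheet gives CPM per library, which the authors made without further scaling, as the values are whole reads divided by the library total. Its mean normalized count, a signal averaged by the authors over all 8 libraries, and the authors' log2 fold changes, standard errors, p-values and adjusted p-values come beside it, per the file headers. Other sheets hold gene lists, with symbols only or with the same values. The sheet lists 1994 genes. The authors' deposited table has a smallest absolute log2 fold change of 0.50, a largest adjusted p of 0.0489 and a lowest mean of 5.00 CPM, and a note in the workbook says that 436 genes with a sample average under 5 were removed. From its p-values and adjusted p-values, 18026 genes had been tested.

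For each library a total was found that turned 100.0% of the CPM values into whole reads within 0.001 reads. Totals ran from 9642436 to 11094287 reads, the lowest count of a listed gene from 2 to 25 reads and the median from 265 to 315 reads. Regressing the authors' mean normalized counts on these reads returned the size factors, 0.98 to 1.02, with a largest misfit of 3.49e-10. Because the listed genes are a selection, count models with their own normalization were not run. Replicate libraries differed by more than sampling noise (chi-square per degree of freedom of 4.70 or more in each pair), so none was counted as a duplicate.

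The main test was limma 3.58.1 (eBayes with trend, R 4.3.3) on log2(CPM + 1), with genotype as the sole term and 2-sided tests. It ran on listed genes only, with Benjamini-Hochberg adjustment over them, as had been fixed for author-normalized values, and a threshold of adjusted p under 0.05 with an absolute log2 fold change of at least 0.5. Fold changes on log2(CPM + 1) understate the change of low genes. Confidence intervals are at 95%. Tested on simulated counts for the 1994 genes, with 200 changed, the step called 70.0% of 50 genes raised 1.5-fold, 68.0% of 50 lowered 1.5-fold, 100.0% of 50 raised 2-fold, 98.0% of 50 lowered 2-fold and 0.06% of 1794 unchanged genes. The simulation gave all genes the same dispersion, left most unchanged and selected none. Its rates therefore do not carry over to calls among genes listed for differing. Gene positions come from GENCODE M21 for mm10, which named 1922 of the listed symbols and not the other 72.

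The 36 gene lists were written before the data were examined: FGF pathway, osteocyte, osteoblast, mineralization, collagen, collagen processing, other matrix proteins, integrin, focal adhesion, actin, matrix turnover, apoptosis, p53 and DNA damage, proliferation, stress response, WNT, axon guidance, junctions, 15 lists of other cell types, immediate early, mitochondrial and sex chromosome genes. Members that rose, fell or did not pass were counted, and Fisher's exact test compared directions (lists with at least 3 listed members). Set tests such as camera and fry need all expressed genes and were not run. Of the listed cell type markers, 2 of 9 osteoclast, 1 of 11 endothelial, 2 of 7 pericyte, 2 of 2 chondrocyte and 4 of 4 tendon markers also stand in another list. Marker scores are the mean log2(CPM + 1) of listed members per library, compared by exact 2-sided permutation tests over 70 assignments, adjusted over the 12 lists. Sheets of the authors were counted without a test, matching symbols without regard to case.

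The tests, the alternatives and the rule for named genes were also fixed then. The rule takes Fgfr1; the 10 that rose most and the 10 that fell most among genes past the threshold with the groups fully apart and a mean normalized count of at least 50, without predicted genes, Rik clones and pseudogenes; up to 4 members per list and up to 3 per sheet with the smallest adjusted p. The mean normalized count was taken from the authors' signal column. Genes outside the rule (Runx2, Spred1, Rspo2, Plk2, Cdkn1a, Dapk1, Csf1r, Cd68, mt-Cytb, Mapk13, Col1a1, Col1a2 and those named only in the closing section) were chosen after their values were seen. Values of some members of the apoptosis and B cell lists are not reported here.

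Alternatives were size-factor rescaling, limma-voom on the recovered reads, pseudocounts of 0.1 and 5, no fold threshold and a threshold of 1, leaving out each library, and marker scores as covariates where a blood or muscle score spanned more than 2-fold between libraries (erythroid 2.67-fold, B cell 2.95-fold, monocyte and macrophage 2.05-fold). Leaving out both libraries that stood apart was added after seeing the data. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The 3 sheets that repeat other sheets were not used.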

Results

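RNA was sequenced from the cortical bone of the femoral shaft of 16-week-old mice, after the marrow had been washed out of the bone. FGFR1-CKO mice carry loxP-flanked Fgfr1 and a tamoxifen-activated Cre recombinase driven by a Dmp1 promoter, which is active in late osteoblasts and osteocytes. The Control genotype names the loxP-flanked gene and no Cre, so the presence of Cre cannot be told apart from loss of Fgfr1 here. All mice ate chow with tamoxifen at 400 mg/kg from 12 weeks of age for 4 weeks. The table held 4 Control and 4 FGFR1-CKO libraries, picked by the submitters from 6 and 7 sequenced samples as those with the highest Fgfr1 (Control) and the lowest (FGFR1-CKO). The Fgfr1 difference was therefore set in part by this choice, and every p-value below is conditional on it. The library totals, recovered from the values, ran from 9642436 to 11094287 reads. The table listed 1994 genes, chosen by the submitters because they differed, which took 24.2% to 35.1% of the reads of a library. A gene outside it is called not listed here, and nothing is said about its level.

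The first question was whether the targeted receptor gene was lower in the mice with Cre. Fgfr1 (ENSMUSG00000031565, mm10 chromosome 8, 25513654 to 25575718) encodes a tyrosine kinase receptor for fibroblast growth factors. It measured 594 ± 71.3 CPM (read counts scaled to the library total; SD, n = 4) in Control and 318 ± 32.1 CPM (SD, n = 4) in FGFR1-CKO, and each FGFR1-CKO library lay below each Control library. The log2 fold change was -0.90 with a standard error of 0.10 (95% confidence interval -1.13 to -0.67, limma adjusted p = 1.87e-05; exact two-sided permutation p = 0.0286, the smallest that 4 against 4 libraries allow). The authors' deposited table gives a log2 fold change of -1.01 for Fgfr1. Between 2665 and 6845 reads lay behind each value. The counts cover the whole gene, so transcripts that lost only the floxed part could still add reads. The osteoblast list moved with Fgfr1: its mean log2(CPM + 1) over 22 genes was 8.42 ± 0.07 (SD, n = 4) in Control and 7.58 ± 0.10 (SD, n = 4) in FGFR1-CKO. Fgfr1 minus this mean was 0.79 ± 0.23 (SD, n = 4) in Control and 0.73 ± 0.15 (SD, n = 4) in FGFR1-CKO, a difference of -0.063 (95% confidence interval -0.33 to 0.20; exact two-sided permutation p = 0.686). With the erythroid score of each library as a covariate, the Fgfr1 log2 fold change was -0.064 (limma adjusted p = 0.924). That score separates the groups, so the fit cannot part it from genotype, and the Fgfr1 standard error widened from 0.10 to 0.37. Over all alternatives the limma adjusted p of Fgfr1 ran from 1.88e-05 to 0.924.

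**Figure D1:**
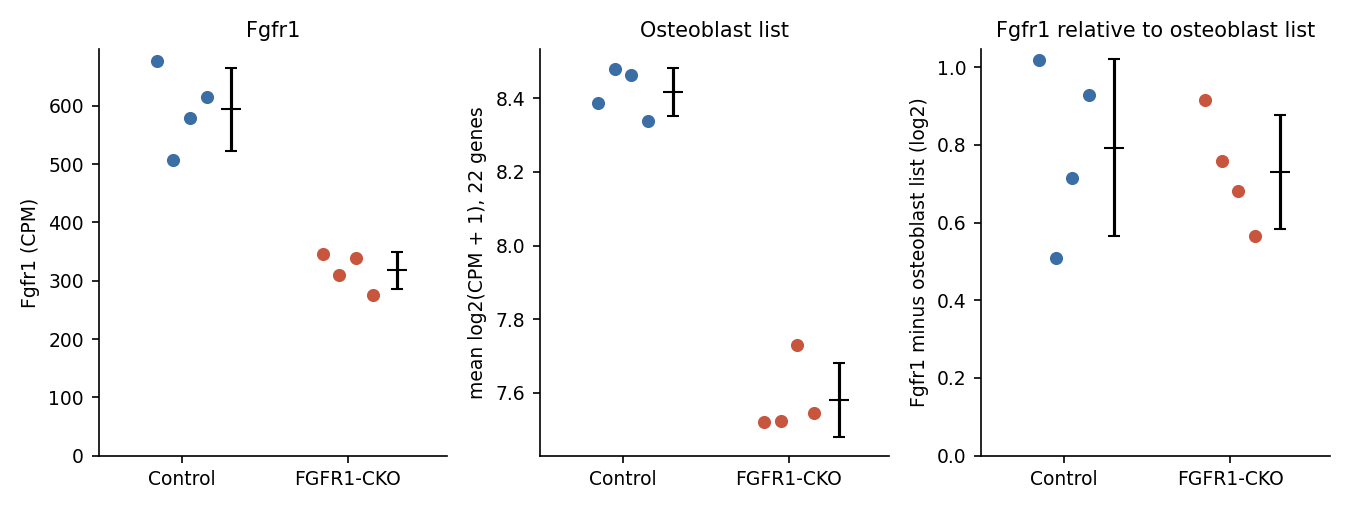
Each point is 1 library (4 Control in blue, 4 FGFR1-CKO in red), with the group mean and SD in black. The panels show Fgfr1 in CPM, the mean log2(CPM + 1) of the 22 listed osteoblast genes on an axis that does not start at 0, and the difference of log2 Fgfr1 and that mean. Fgfr1 fell from 594 to 318 CPM, while its level relative to the osteoblast list was 0.79 and 0.73.

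The second question was which genes differed between the genotypes. Genes of bone cells and bone matrix were lower in FGFR1-CKO bone, and genes of red blood cell precursors, histones and cell division were higher. The authors' deposited table holds 1994 genes, 1265 lower and 729 higher in FGFR1-CKO. In the limma fit of the CPM values, 1495 of these passed an adjusted p of 0.05 with an absolute log2 fold change of at least 0.5, of which 729 rose and 766 fell. The 499 that did not pass were all lower genes. At any fold change 1983 had an adjusted p under 0.05, so most of the 499 missed only the fold threshold. Fold changes of this fit lay a median of 0.12 above the authors', whose smallest absolute value was 0.50. A listed gene that did not pass may therefore still differ. All 1994 had the direction of the authors' deposited table. Rescaling the libraries by size factors shifted the log2 fold changes by a median of -0.11, and 651 then rose and 1154 fell, so that the share that fell moved from 51.2% to 63.9%. Without both libraries that stood apart (Control replicate 4 and FGFR1-CKO replicate 3), 717 rose and 669 fell. With the erythroid score as a covariate limma called 0 genes at any fold change, and 497 had an unadjusted p under 0.05. Because that score separates the groups, this fit cannot part it from genotype. The adjusted p-values were taken over listed genes only, which had been selected for differing.

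The 10 named genes that rose most were led by Olfm4, a granule protein of neutrophils, from 25.9 ± 3.94 to 93.8 ± 15.0 CPM (SD, n = 4 per group), a log2 fold change of 1.82 with a standard error of 0.13 (limma adjusted p = 5.45e-06). Osm, which encodes the cytokine oncostatin M, rose from 6.00 ± 0.61 to 19.6 ± 3.44 CPM (SD, n = 4 per group), a log2 fold change of 1.55. The globin genes Hbb-bs, Hba-a2 and Hba-a1 rose by log2 fold changes of 1.47, 1.44 and 1.43. Car1, a carbonic anhydrase of red cells, rose by 1.37 and Gdpd3 by 1.37, the latter with a standard error of 0.35. The histone genes H4f16 (1.68) and H2bu2 (1.56) and the cystatin-family gene Cstdc5 (1.46) also belonged to the 10. Globin, histone and cystatin genes have near-identical copies, so the counts of a single one are uncertain.

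Eps8l1, a relative of the actin regulator Eps8 (mm10 chromosome 7, 4460674 to 4480487), fell most of the 10 named on this side. It measured 13.3 ± 4.78 CPM in Control and 1.08 ± 0.39 CPM in FGFR1-CKO (SD, n = 4 per group), a log2 fold change of -2.71 on the log2(CPM + 1) scale with a standard error of 0.26 (limma adjusted p = 8.9e-06). Only 6 to 15 reads per FGFR1-CKO library lay behind it, against 66 to 174 in Control. Fosb, an immediate early transcription factor, had a log2 fold change of -1.70 with a standard error of 0.39. The matrix proteoglycans Lum (-1.42) and Omd (-1.28), the secreted factor Serpinf1 (-1.37), the collagenase Mmp13 (-1.30), Fam167a (-1.29), Ranbp3l (-1.25), the collagen-associated Cthrc1 (-1.23) and the osteocalcin-family gene Bglap2 (-1.21) completed the 10. Bglap2 shares sequence with its neighbouring copies, so its own count is uncertain.

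Of 36 gene lists fixed in advance, 32 had listed members and 29 had at least 3, the minimum for a test. Fisher's exact test of the share of members that were lower, against the other listed genes, passed an adjusted p of 0.05 for 19. The test counts each listed member by sign, whereas rose and fell below mean past the threshold. By sign all 10 focal adhesion, 11 endothelial, 31 axon guidance, 40 other matrix and 6 integrin genes listed were lower. Counts of members past the threshold adjusted over the list alone equalled those over all listed genes in 32 of 32 lists. Only genes that had already passed the submitters' threshold enter these tests, so they compare directions, not how often a list changed. They also count genes as separate units, although genes measured in the same 8 libraries can move together. Their p-values, however small, do not measure the spread between libraries.

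Osteoblast genes fell almost as a block. Of 23 members 22 were listed and 21 fell (median log2 fold change -0.75, Fisher adjusted p = 2.42e-04). Spp1 (osteopontin) fell by 1.13 on the log2 scale, Dlx3 by 0.77, Cdh11 by 0.74 and Ibsp (bone sialoprotein) by 0.68. Runx2, the transcription factor that starts osteoblast differentiation, did not pass (log2 fold change -0.40). After size-factor rescaling all 22 listed members fell, Runx2 among them. Of 18 osteocyte genes 10 were listed and 9 fell (adjusted p = 0.0303), including the potassium channel gene Kcnk2 (-0.998), Fbln7 (-0.96), Gja1 (connexin 43, -0.93) and Dmp1 (-0.62), whose promoter drives the Cre. In the mineralization list 16 of 18 listed members fell (adjusted p = 1.05e-03), with Mgp at -1.06 and Sparc (osteonectin) at -1.02. The same libraries carried an erythroid score that was 1.08 higher and a neutrophil score that was 0.68 higher in FGFR1-CKO, both as differences of mean log2(CPM + 1).

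Genes that make, modify and degrade the matrix fell too. In the collagen list 20 of 22 listed members fell (median -0.82, adjusted p = 2.42e-04), among them Col6a2 (-1.12), Col8a2 (-0.95), Col24a1 (-0.94) and Col27a1 (-0.59). Col1a1 and Col1a2, the chains of collagen I, together took 12.1% to 17.2% of the reads in Control and 6.77% to 11.2% in FGFR1-CKO. Of the collagen processing genes 20 of 22 fell (adjusted p = 2.42e-04), for example the crosslinking enzymes Loxl1 (-0.76) and Loxl3 (-0.63) and the collagen chaperone Fkbp10 (-0.75) and Crtap, a partner of a prolyl hydroxylase (-0.63). Of 40 listed other matrix proteins 24 fell and 16 did not pass (adjusted p = 1.18e-07), with Fbln1 at -1.16, Ccn5 at -0.88, Dcn (decorin) at -0.77 and Efemp2 at -0.71. After size-factor rescaling 39 of these 40 fell. The matrix turnover list had 17 genes that fell and 1 that rose of 21 (adjusted p = 3.25e-03). Adam12 (-1.04), Mmp14 (-0.79) and Fap (-0.74) fell, and the rise was in Adam8 (0.81), a metalloprotease of white blood cells. The erythroid score was again 1.08 higher in these FGFR1-CKO libraries.

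Members of the FGF list were lower as well. Of 35 members 9 were listed, and 8 fell (adjusted p = 0.0471), while Spred1, a feedback inhibitor, did not pass (-0.47). After size-factor rescaling all 9 fell. Besides Fgfr1 the 8 included Fgfr3 (-0.81), the ligand gene Fgf1 (-0.79) and Fgfr2 (-0.54). Without both libraries that stood apart 4 fell. In the WNT list 13 of 17 fell and 1 rose (adjusted p = 0.0210). Wif1 (-0.95), Sfrp1 (-0.73), Tcf7l1 (-0.55) and Fzd8 (-0.52) fell, and Rspo2, a secreted WNT enhancer, rose (0.88). The immediate early list had 5 of 7 that fell, among them Egr1 (-0.95), Egr2 (-0.58) and Jun (-0.56), with a direction test that did not pass (adjusted p = 0.0724). In the same libraries the osteoblast score was 0.84 lower and the erythroid score 1.08 higher in FGFR1-CKO.

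In the integrin list 4 of 6 listed members fell (Itga11 at -0.83, Itga10 at -0.64, Itgav at -0.55 and Itga9 at -0.51), and the direction test did not pass (adjusted p = 0.116). Of 10 listed focal adhesion genes all 10 were lower by sign (adjusted p = 0.0303). Past the threshold 5 fell, including Parva (-0.66), Tns2 (-0.57), Bcar1 (-0.56) and Tln2 (-0.50). That count was 8 after size-factor rescaling, 3 without Control replicate 1 and 3 without FGFR1-CKO replicate 3. Without both libraries that stood apart, 2 integrin and 2 focal adhesion genes fell. The actin list went both ways, with 5 that fell (Fscn1 at -0.64, Cald1 at -0.52) and 2 that rose (Diaph3 at 0.68, Ezr at 0.60) of 11 (adjusted p = 0.387). After size-factor rescaling 9 fell and 1 rose. Of gap junction and cadherin genes 8 of 10 fell (adjusted p = 0.0303), such as Gjc1 (-0.95) and Cdh2 (-0.83). Axon guidance and neurite genes fell in 23 of 31 listed cases (median -0.61, adjusted p = 8.62e-06). Epha3 (-1.12), Plxna2 (-1.09), Slit3 (-0.74) and Dpysl3 (-0.69), genes of guidance cues, their receptors and their effectors, were the named examples. Beside these groups the endothelial score was 0.50 lower and the erythroid score 1.08 higher in FGFR1-CKO.

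Genes of cell division rose without exception. All 34 proliferation genes were listed and 34 rose (median 0.77, range 0.60 to 1.07, adjusted p = 2.44e-14), among them the cyclins Ccne1 (1.07) and Ccna2 (0.95), the replication licensing factor Mcm5 (0.88) and Birc5 (survivin, 0.81). Of 10 listed p53 and DNA damage genes 8 rose and 1 fell (adjusted p = 0.0170). H2ax (1.00), Gadd45a (0.81), Brca1 (0.79) and Btg2 (0.74) rose, Plk2 fell (-0.58), and Cdkn1a, the classic p53 target, did not pass (-0.47). After size-factor rescaling 6 of the 10 rose and 2 fell, Cdkn1a among the latter. Of 51 apoptosis genes 4 were listed and 3 rose (adjusted p = 0.171). Among these were Bnip3l (0.87), which removes mitochondria in maturing red cells, and Birc5, an inhibitor of cell death that acts in mitosis. Dapk1 did not pass (-0.38). Of 27 stress response genes 5 were listed and 4 rose (adjusted p = 0.0830): Hmox1 (0.93), the glutathione synthesis genes Gclm (0.72) and Gclc (0.66), and Asns (0.62). The erythroid and neutrophil scores were 1.08 and 0.68 higher in the same libraries.

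**Figure D2:**
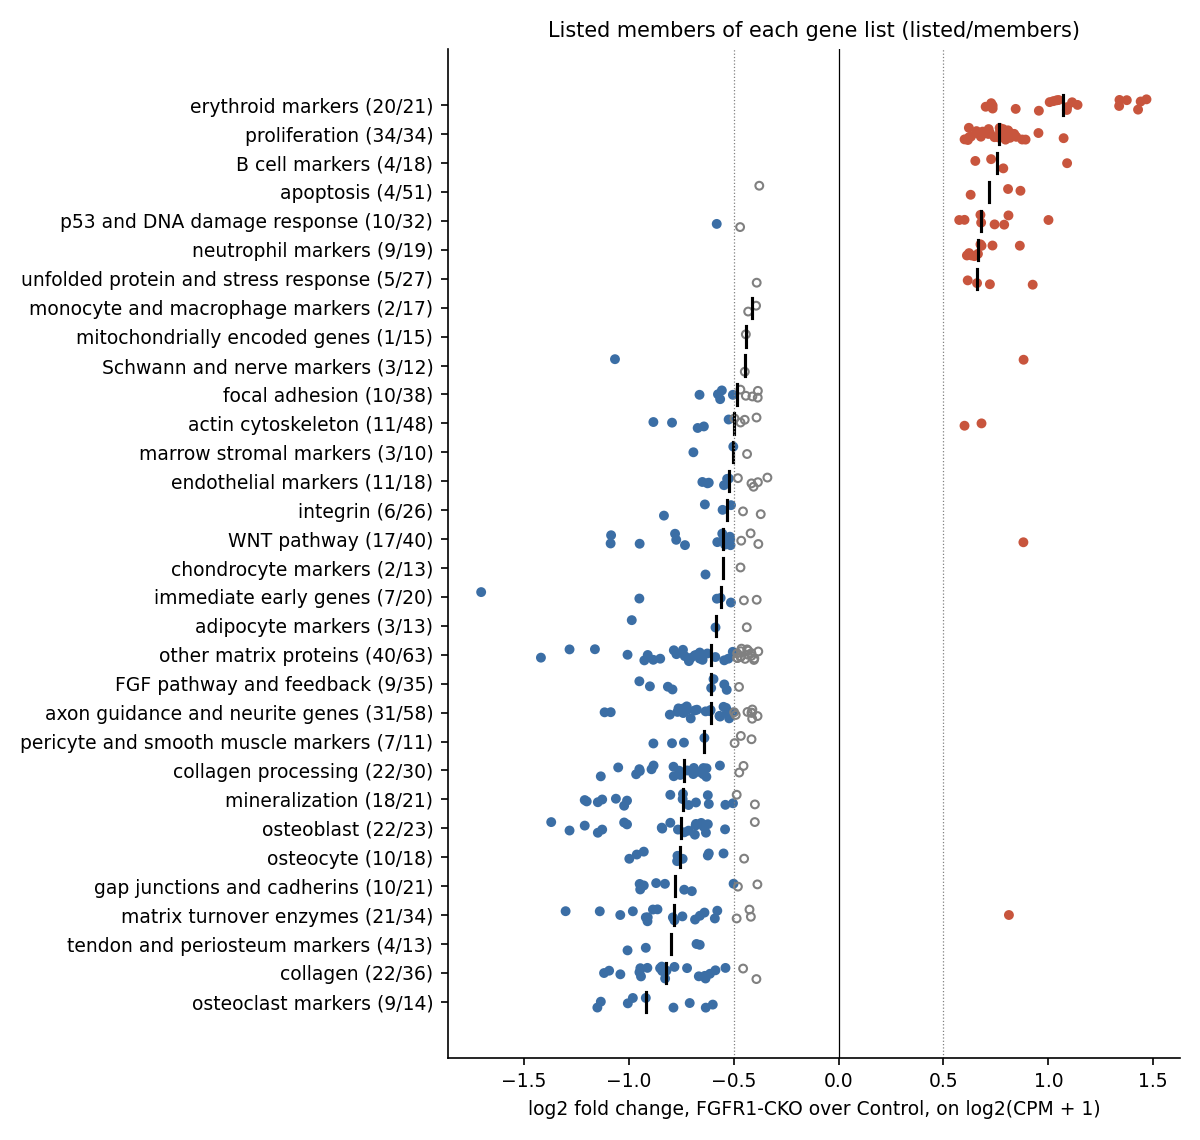
Each point is 1 listed gene, at its log2 fold change of FGFR1-CKO over Control on log2(CPM + 1). Filled red and blue points passed the threshold upward and downward, open points did not pass, black bars are list medians and dotted lines mark 0.5 in either direction. All 34 proliferation and 20 erythroid genes lie to the right, and 21 osteoblast genes are filled to the left. The gap around 0 arises because the table holds only genes selected for differing.

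The flushed bone can hold blood, vessel and other cells, so markers of 15 other cell types and the sex chromosome genes were averaged in each library. Scores of 12 lists could be formed, and 10 differed at an adjusted p of 0.0343, each with an exact two-sided permutation p of 0.0286, the smallest possible. Only listed members enter a score, and these were chosen for differing between the same libraries. Of all listed genes, 90.5% had the groups fully apart. The permutation p-values of the scores therefore do not test whether a cell type changed. Erythroid markers were listed in 20 of 21 cases and 20 rose (score 7.05 ± 0.19 in Control, 8.13 ± 0.08 in FGFR1-CKO, SD, n = 4; Fisher adjusted p = 2.23e-08). Alas2, the first enzyme of haem synthesis in red cells, had a log2 fold change of 1.34, Car1 1.37 and the erythroid transcription factor Klf1 1.14. Of 19 neutrophil markers 9 were listed and 9 rose (score difference 0.68, Fisher adjusted p = 4.1e-04), with Camp at 0.86, S100a9 at 0.73, Cebpe at 0.63 and Ly6g at 0.61. The B cell list had 4 of 18 listed, and 4 rose (score difference 0.81, Fisher adjusted p = 0.0303), among them Igll1 at 1.09 and Pax5 at 0.73. No T and NK cell, megakaryocyte, skeletal muscle or sex chromosome gene was listed.

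Scores of cells that live on or in bone were lower over their listed members, which had been selected for differing. They do not measure a cell type as a whole. Only 2 of 13 chondrocyte and 2 of 17 monocyte and macrophage markers were listed, for example. The osteoclast score was 0.88 lower, and 9 of 9 listed osteoclast genes fell (Fisher adjusted p = 0.0471), with Ocstamp at -1.15, Oscar at -1.13, Atp6v0d2 at -1.005 and Ckb at -0.79. Control replicate 4 stood apart (score 6.78, other Controls 5.75 to 5.98), and 7 of 9 fell without both it and FGFR1-CKO replicate 3. The endothelial score was 0.50 lower, and 6 of 11 listed genes fell (Fisher adjusted p = 0.0210), such as Ptprb (-0.65), Sox18 (-0.62), Emcn (-0.55) and Tek (-0.52). That count was 3 without Control replicate 1. The pericyte and smooth muscle score was 0.63 lower with 4 of 7 genes that fell (Myh11 at -0.88, Acta2 at -0.79, Rgs5 at -0.74, Pdgfrb at -0.64; Fisher adjusted p = 0.0724), and 7 of 7 fell after size-factor rescaling. The tendon and periosteum score was 0.82 lower with 4 of 4 (Postn at -1.01, Ctsk at -0.92, Fmod at -0.68, Aspn at -0.66; Fisher adjusted p = 0.352), but all 4 are also members of other lists, Ctsk as a protease of osteoclasts. Marrow stromal genes fell in 2 of 3 cases (Pdgfra at -0.69, Igfbp5 at -0.50; score 0.54 lower; Fisher adjusted p = 0.578), a count of 1 when Control replicate 1, Control replicate 4, FGFR1-CKO replicate 3 or FGFR1-CKO replicate 4 was left out singly. Chondrocyte genes fell in 1 of 2 cases (Col11a2 at -0.64; score 0.55 lower), with 2 without Control replicate 2, FGFR1-CKO replicate 1 or FGFR1-CKO replicate 2. Csf1r (-0.43) and Cd68 (-0.39), the listed monocyte and macrophage markers, did not pass singly, and their score was 0.41 lower. After size-factor rescaling both fell past the threshold. Adipocyte (0.67 lower) and Schwann cell (0.21 lower) scores did not pass, both with an adjusted p of 0.0857 by exact permutation test. Plin1 (-0.99) and Plin4 (-0.59) were the adipocyte genes that fell, and the count was 0 without Control replicate 1 or Control replicate 3, and 1 without Control replicate 4, FGFR1-CKO replicate 3 or FGFR1-CKO replicate 4 (Fisher adjusted p = 0.578). In the Schwann list S100b fell (-1.07) and Gfap rose (0.88) of 3 listed genes (Fisher adjusted p = 1), and 2 fell without Control replicate 3. The only listed mitochondrially encoded gene, mt-Cytb, had a log2 fold change of -0.44 and did not pass, but passed without Control replicate 2 or FGFR1-CKO replicate 4.

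**Figure D3:**
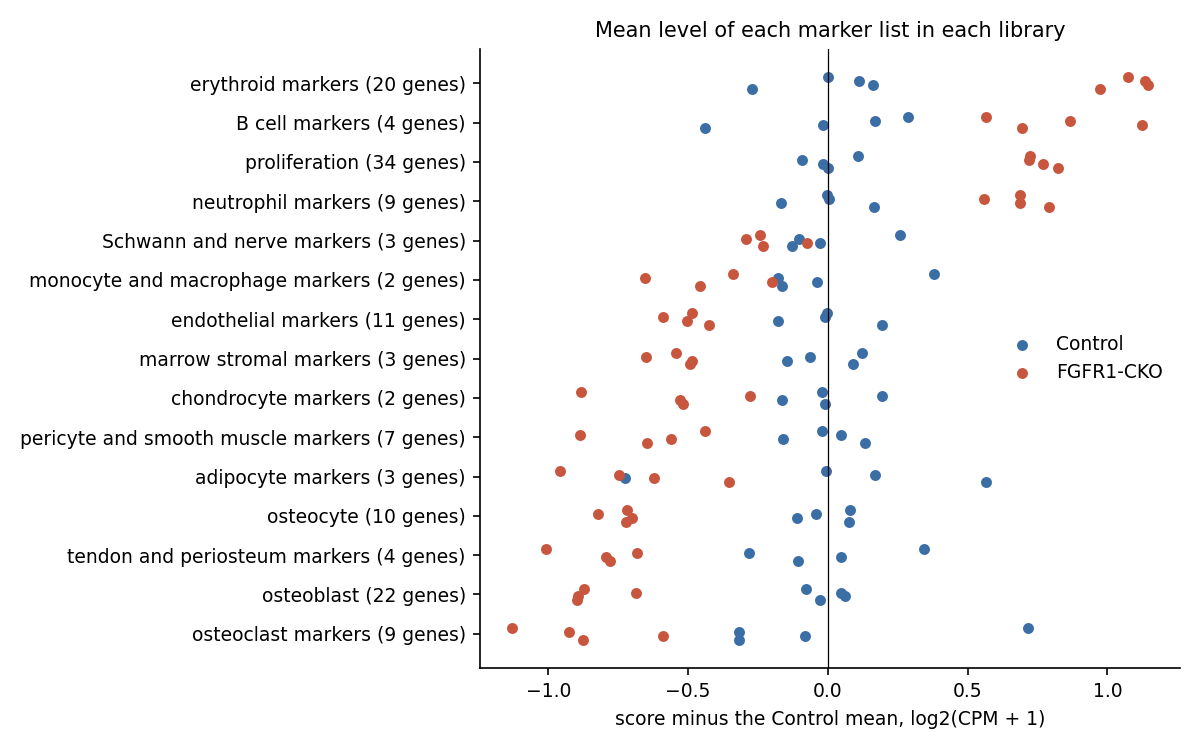
Each point is 1 library, at the mean log2(CPM + 1) of the listed genes of a marker list minus the Control mean of that list. Control is blue and FGFR1-CKO red, with 4 libraries each. FGFR1-CKO libraries lie to the right for erythroid (1.08), B cell (0.81), proliferation (0.76) and neutrophil (0.68) genes and to the left for osteoblast (-0.84) and osteocyte (-0.74) genes.

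The workbook also held thematic gene sheets, which the authors chose on these libraries, so their directions are no independent evidence. In the sheet of matrix organization genes 55 of 72 fell (median -0.69), and in that of cell migration genes 44 of 72 fell (median -0.53), with Cemip (-0.93), Mmp14 (-0.79) and Sash1 (-0.70) leading by p. In the neuron development sheet 65 of 105 fell (median -0.53), among them Epha3 and Ndrg4 (-0.77). These counts are of genes past the threshold. By sign all 72 matrix organization, all 72 cell migration and all 105 neuron development genes were lower. The cell cycle and stress sheet had 124 matched genes, of which 124 rose (median 0.71), led by Cdc25b (1.07) and Cdc6 (1.04). The apoptosis sheet was mixed, with 9 of 26 that rose, such as Ppp1r15a (0.75), and 13 that fell (17 lower by sign). A second set of sheets, whose prefix the labels do not explain, is named for lower matrix, mineral, collagen, integrin, focal adhesion and cytoskeleton genes. There 63 of 75 listed matrix genes fell, as did 35 of 38 biomineralization genes (Gli3 at -1.01, Pmepa1 at -0.88), 35 of 37 collagen genes, 29 of 42 integrin genes, 29 of 44 focal adhesion genes and 33 of 54 cytoskeleton genes (Pls3 at -0.66, Myo1e at -0.60). Medians were -0.74, -0.79, -0.76, -0.63, -0.55 and -0.52 in that order, and by sign 74, 38, 37, 42, 43 and 54 genes were lower. The focal adhesion sheet also held Osm, which rose (1.55), and the matrix sheet Mapk13, which rose (0.73) and was picked out after its value was seen.

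The last comparison set the mouse table beside gene lists from Ocy454, a mouse osteocyte-like cell line. The lists are headed as higher with BGJ or higher with FGF2, in 3 pairs whose conditions the headers do not give. They held 192 and 231 genes in all, with 0 in both. In bone, 80 genes of the BGJ lists were listed, of which 64 fell and 4 rose. Of the FGF2 lists 41 were listed, of which 24 fell and 2 rose. By sign alone 95.0% and 95.1% were lower in FGFR1-CKO, against 61.4% of the other 1873 listed genes. No difference in direction between the BGJ and FGF2 lists was found (Fisher's exact p = 1). If higher with BGJ is matched with higher in FGFR1-CKO, 43 of 121 genes had the same direction (35.5%), a share that follows from the sizes of the 2 lists, since both were mostly lower. Of the combined list of 627 genes 183 were listed, 170 lower and 13 higher by sign, with Adam12 (-1.04), Cemip (-0.93) and Cd24a (0.91) leading by p. A pair of further sheets names Ocy454 genes by theme: 18 of 23 listed neuron genes (Fat4 at -0.80, Cdh2 at -0.83, Slit3 at -0.74) and 20 of 24 listed matrix genes (Serpinh1 at -1.13, Col8a2 at -0.95, Col27a1 at -0.59) fell in FGFR1-CKO bone. All 23 and all 24 were lower by sign.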

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

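All tests of explanations in this part were chosen after the results they bear on had been seen, except the count over other splits of the libraries.

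Genes of bone, vessel and matrix were lower while erythroid, neutrophil, B cell and proliferation genes were higher in FGFR1-CKO. Size-factor rescaling cannot decide whether the smaller share of collagen reads was the whole cause of the rise. It shifts fold changes by a median of -0.11. The erythroid list then kept a median log2 fold change of 0.96 (median of the single-gene lower bounds 0.66). The authors had listed genes by fold changes of at least 0.50 in absolute value on that same scaling, so a median near 0 could not occur. A larger share of marrow RNA with unchanged composition may account for part of the pattern. It cannot be told apart from a change within the blood cells. The erythroid minus neutrophil score was -1.63 ± 0.32 in Control and -1.23 ± 0.17 in FGFR1-CKO (SD, n = 4, exact permutation p = 0.0571). The monocyte and macrophage score was 0.41 lower (exact permutation p = 0.0286), against higher erythroid and neutrophil scores. It cannot decide whether the composition changed. That score rests on 2 genes, Csf1r and Cd68, which were listed for differing and which osteoclasts also express. One common dilution of all bone-resident cells stays open in the same way, with an osteoblast minus endothelial score of 2.81 ± 0.20 and 2.47 ± 0.16 (SD, n = 4, exact permutation p = 0.0571). The table's fold threshold limits these score tests too, and an effect of the genotype on bone and blood cells themselves was not tested apart from them.

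Fgfr1 and the osteoblast list were both lower in FGFR1-CKO. Relative to that list the difference was -0.063 (95% confidence interval -0.33 to 0.20), and the interval excludes a drop of -0.45, which is 0.5 of the Fgfr1 fall, so the amount of osteoblast RNA in a library may carry much of the fall. Relative to the osteocyte list the difference was -0.16 (exact permutation p = 0.200), and subtracting the osteoblast score did not narrow the spread of Fgfr1 within Control (SD 0.18 before and 0.23 after, n = 4). Fgfr1 minus the endothelial score was 3.60 ± 0.04 in Control and 3.20 ± 0.17 in FGFR1-CKO (SD, n = 4, exact permutation p = 0.0286), which leaves a change in vessel RNA open, because the libraries had been picked by their Fgfr1 level and this lowers such a difference by itself. Loss of Fgfr1 from cells together with lower osteoblast genes in those cells stays open as the biological explanation.

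Proliferation genes were higher in 4 of 4 FGFR1-CKO libraries. Dividing erythroid precursors are a candidate source: the proliferation minus erythroid score was -1.21 ± 0.23 in Control and -1.53 ± 0.12 in FGFR1-CKO (SD, n = 4), a difference of -0.32 (exact permutation p = 0.0857). The difference lies on the side of a smaller proliferation rise, but a p that misses the threshold leaves division of other cells open, and the 2 sources cannot be told apart. Of the 34 proliferation genes most are expressed in any dividing cell.

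The real grouping called 1495 listed genes and the highest of the other splits 13, with 1 of 35 splits at the real count. Because the genes had been listed for differing in the real grouping, this count says nothing about chance.

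Libraries far from the other 3 of their group were found in 24 of 304 groups of values examined (7.89%), where chance gives about 5%. Control replicate 4 had the highest osteoclast genes, with Ctsk at 1274 CPM (others 590 to 667), Atp6v0d2 at 122 CPM and Ocstamp at 28.3 CPM, and also Cdc6 at 26.5 CPM, with low Loxl1 (165 CPM), Bnip3l (94.6 CPM) and Plxna2 (174 CPM). FGFR1-CKO replicate 3 had the highest share of collagen I reads (11.2%, others 6.77% to 7.21%), osteoblast score (7.73, others 7.52 to 7.54) and Col11a2 (2318 CPM), and the lowest Ezr (117 CPM). In FGFR1-CKO replicate 4, Cald1 (121 CPM), Adam12 (86.2 CPM) and Plxna2 (118 CPM) were highest and H2bu2 (39.9 CPM) and Gclm (100.1 CPM) lowest of the group. Slit3 was highest in FGFR1-CKO replicate 2 (169.6 CPM). Control replicate 1 had high Mgp (99.4 CPM) and low Itga10 (55.0 CPM) and Gfap (4.25 CPM), Control replicate 2 low Tns2 (95.5 CPM), Btg2 (48.9 CPM) and Cebpe (47.0 CPM), and Control replicate 3 low Gli3 (31.6 CPM).

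Outside the main table, the thematic sheets held values of 6 genes that were lower in FGFR1-CKO with folds under its threshold. Itga5 measured 68.1 ± 2.7 and 54.3 ± 1.13 CPM, Itgb1 407 ± 33.2 and 318 ± 16.9 CPM, and Src 91.9 ± 7.34 and 70.5 ± 3.96 CPM in Control and FGFR1-CKO (SD, n = 4 per group). Ank3, Kifc3 and Ano6 were the other 3.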

How the results depend on the processing

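Leaving out both libraries that stood apart was chosen after the data had been seen. Fgfr1 kept its direction in each fit and its call in all but the erythroid covariate. Its log2 fold change ran from -0.97 to -0.83 when each library was left out. Over the same 8 fits, 1426 to 1563 genes passed, 715 to 725 higher and 701 to 842 lower. The genes had been listed for differing over all 8 libraries, so most calls were bound to stay. The direction tests of the lists rest on signs that the selection of the genes had all but set, so their count tests no setting. Pseudocounts, limma-voom and the size factors ended the call of at most 9 of 132 named genes, leaving out single libraries of at most 11. The B cell covariate ended the calls of 24 and the monocyte and macrophage covariate those of 19 named genes. The 10 marker scores that passed were 10 with medians or a pseudocount of 5, a count that the selection of their members had all but set. At an absolute log2 fold change of at least 1 the share of Ocy454 genes with the same direction was 11.1% of 9, which follows from the sizes of the lists. No paired analysis was possible because the labels give no replicate numbers, and those used here only follow accession order. DESeq2, edgeR, camera and fry were not run, nor a change of the low-value filter, because the table was filtered by the authors and each gene has a mean normalized count over 50. Depth limits genes with few reads, such as Eps8l1.

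With the erythroid score as a covariate 0 genes passed (0 higher, 0 lower), and Fgfr1 had a log2 fold change of -0.064. At an unadjusted p under 0.05 limma counted 497. The score separates the groups, so the fit cannot part it from genotype. Fold changes moved (Fgfr1 from -0.90, and 16 of 132 named genes turned sign), and the median standard error widened from 0.10 to 0.41. At a fold threshold of 1, 121 genes passed (71 higher, 50 lower). With no threshold 1254 were lower, and 1154 after size-factor rescaling, which shifts the fold changes by a median of -0.11. That rescaling also moved the number of members that fell to 39 for other matrix proteins, 8 for focal adhesion, 9 for actin, 2 for monocyte and macrophage, 7 for pericyte and smooth muscle, 2 for chondrocyte, 2 for Schwann cell and 1 for mitochondrial genes. With it 30 axon guidance, 15 WNT, 9 endothelial and 5 integrin genes fell. Without both libraries that stood apart the FGF list had 4, integrin 2, focal adhesion 2, adipocyte 1 and marrow stromal 1. With limma-voom adipocyte genes had 1. Leaving out each library gave 3 to 6 focal adhesion, 3 to 7 endothelial, 0 to 3 adipocyte, 1 to 3 marrow stromal, 1 to 2 chondrocyte, 1 to 2 Schwann cell and 0 to 1 mitochondrial genes that fell. Beyond fewer samples the cause was not tested.

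Signs turned with covariates, none of them past the threshold, and the cause was not tested. With the erythroid score the log2 fold changes were -0.054 for Hba-a2, 0.023 for Ranbp3l, 0.48 for Fgf1, 0.15 for Tln2, -0.068 for Alas2, -0.10 for Igll1, -0.54 for Pax5, -0.99 for Vpreb3, 0.061 for Ptprb, 0.47 for Tek, 0.37 for Emcn, 0.51 for Rgs5, 1.79 for Plin4, 2.01 for Plin1, 0.52 for Igfbp5 and 0.31 for Jun. With the B cell score they were -0.069 for Pax5, -0.24 for Vpreb3 and 0.27 for Plin4.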

Other observations

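The tests in this part were chosen after the data had been seen. Histone genes of the replication-dependent clusters, whose transcripts lack a poly(A) tail and are kept by a library primed with random hexamers, formed a large block of the higher genes. Of 54 listed, 54 rose (median log2 fold change 0.95, range 0.70 to 1.68), against 34.8% higher among the other 1940 listed genes (Fisher's exact p = 6.96e-25). The family was picked after the table was seen, and how reads of its near-identical members were assigned is not known. The Fisher test also counts them as separate units. In the same libraries the proliferation score was 0.76, the erythroid score 1.08 and the neutrophil score 0.68 higher.

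Set against the osteoblast list in the same library, 3 listed genes fell further by at least 0.5. Eps8l1 fell by 1.88 beyond it on the log2 scale (limma adjusted p = 5.2e-06), Lum by 0.58 (adjusted p = 5.75e-03) and Serpinf1, a member of the list that was set against the other members, by 0.56 (adjusted p = 4.39e-03). Relative to that list, with members of both left out, FGF genes differed by 0.15, immediate early genes by 0.10, osteocyte genes by 0.096, mineralization genes by 0.15, collagen genes by 0.061 and osteoclast genes by -0.043 between the groups (exact permutation p from 0.114 to 0.914). Only listed members enter, such as 9 of 35 FGF and 10 of 18 osteocyte genes, and these were selected for differing between the same libraries. The permutation p-values here therefore cannot show whether a list follows the osteoblast genes. Among the lists with mostly lower genes, some differed more: Schwann cell genes by 0.63, actin genes by 0.47 and WNT genes by 0.27 (exact permutation p = 0.0286, adjusted p = 0.0800), endothelial genes by 0.34, integrin genes by 0.28 and other matrix proteins by 0.20 (exact permutation p = 0.0571). The Schwann cell (2 lower, 1 higher), actin (9 lower, 2 higher) and WNT (16 lower, 1 higher) lists held genes of both signs. Their means mix genes that rose, such as Gfap (0.88) in the Schwann list, with genes that fell. With 4 libraries per group and 28 lists the adjusted p had little room to pass 0.05, as erythroid genes, which differed by 1.92, also had 0.0800. Eps8l1 lay between 6.29 and 17.2 CPM in Control and between 0.61 and 1.44 CPM in FGFR1-CKO.

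If BGJ is taken as an inhibitor of FGF receptors, genes raised by it in Ocy454 cells could be expected to rise in FGFR1-CKO bone and genes raised by FGF2 to fall. Of 80 shared BGJ genes 76 were lower by sign and 4 higher, so the listed ones did not rise as a set. Of 41 shared FGF2 genes 39 were lower, and no difference in direction between the lists was found (Fisher's exact p = 1). Why the BGJ genes were lower cannot be decided here. The genes were listed for differing between the groups, and both lists hold genes that the cell line expresses, so both may follow the bone cell content of the libraries.

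From the ratio of p to adjusted p, the listed gene with the largest adjusted p stood at rank 4957 of the 18026 genes tested in the authors' deposited table, so at least 27.5% of tested genes had an adjusted p under 0.05 at some fold. In the integrin sheet, the column headed sample average equals the mean of 14 columns, statistics included, in 45 of 45 genes within a relative difference of 1e-06. For Fgfr1 it reads 597 against a mean of 456 CPM over the 8 libraries.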
